A study of Arabidopsis thaliana with 6 samples.

How the data were processed

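Total RNA of 3-week-old Arabidopsis thaliana plants was extracted with a column kit and hybridised as biotin-labelled target to Affymetrix arrays, per the labels' protocols. There were 2 arrays each of camta3-1, camta3-2 and wild type, which the labels call biological replicates. The tissue is not given in the sources used here. The deposited values are log2 expression values per probe set, one column per array, processed with RMA (which corrects background, makes the arrays' distributions alike and summarises probes into probe sets) and Partek, per the submitters' processing notes. Versions of these tools are not given in the sources used here. RMA shrinks differences of dim probe sets, and making distributions alike removes any shift shared by all transcripts.

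The deposited table held 22810 probe sets, of which 64 controls were left out and 22746 were tested without a filter on dim values. The platform annotation named 1 gene for 13513 probe sets, several for 503 and none for 8730. Of the probe sets with 1 gene, 13436 had a locus in the reference gene table (assembly TAIR10.1), covering 13286 loci. Symbols were taken from that table, which was used for names and gene order alone. A gene with several probe sets was represented by the one with the highest mean. No genes were named for the other probe sets, so many well-known defence markers, among them the listed pathogenesis-related genes, and CAMTA3 itself, were not analysed here. The search for CAMTA binding elements in promoters was not analysed here, because it needs a genome.

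Groups were compared with limma 3.58.1 in R 4.3.3, using a linear model with 1 mean per group over all 6 arrays, contrasts and empirical Bayes moderation, with 3 residual and 4.43 prior degrees of freedom. Fold changes are differences of log2 means, and p-values were adjusted by Benjamini-Hochberg over the 22746 probe sets, with a threshold of 0.05. The 4 contrasts were the mean of both alleles minus wild type, each allele minus wild type, and camta3-2 minus camta3-1. Before the data were examined, 19 gene lists, the rule for named genes and the alternatives were fixed. Named genes were the CAMTA family and landmark defence genes, the 15 largest rises and 10 largest falls for that mean among probe sets with 1 gene that passed with all 4 mutant arrays on one side of both wild-type arrays, the 5 largest changes per direction in each allele and between alleles, and up to 4 members of each list with the smallest p. The 28 families were written later, by symbol pattern or by locus identifiers recalled without a curated table, before any fold change was computed, and the rule for up to 4 members was extended to them after the top genes had been looked at. Other genes named in the closing section were chosen after their values were seen.

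Lists with at least 5 measured genes were tested with camera, with a preset correlation of 0.01 and Benjamini-Hochberg over the lists, also with an estimated correlation and with fry. Alternatives were a replicate block, cyclic loess, median centring, a filter at the 40th percentile of means (log2 5.33), a trended and robust prior, an unmoderated test, array weights, fits of 2 groups, pooled mutants, stricter thresholds, probe sets with 1 gene, and leaving out each array. Agreement of the alleles was set against 100 simulated data sets of unchanged groups that share the wild-type arrays. In these and all further simulations the probe sets were drawn independently of each other. After the agreement had been seen, 100 simulations each with independent mutant arrays and with same-numbered mutant arrays correlated at 0.402 were added, in which the probe sets with the smallest p were taken in lists as long as those observed. The wild-type arrays were also divided, with a different one for each allele. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

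The test was run on simulated data with 200 changed probe sets among 22746. For the mean of both alleles against wild type, 98% of changes of 1 on the log2 scale and 100% of changes of 2 were found, and 18 of 216 calls were unchanged probe sets. For camta3-1 the shares were 95% and 100% with 20 of 215 calls unchanged, and for camta3-2, 93% and 100% with 10 of 203. For the difference between alleles, where nothing was changed, 2 were called. The camera step called 1 of 1 raised and 0 of 20 unchanged lists. The threshold expects 5% of calls to be false, which was exceeded for the mean of both alleles and for camta3-1. The arrays were drawn independently, with the moderated variances of the fit, while same-numbered mutant arrays correlated at 0.402. The shares found can therefore be too high for the real arrays.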

Results

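Transcript levels were measured on Affymetrix oligonucleotide arrays in Arabidopsis thaliana plants that were 3 weeks old. CAMTA3 is a calmodulin-binding transcription factor, known as a repressor of salicylic acid-dependent defence genes. The 6 arrays fell into 3 groups of 2 biological replicates each, which were the mutant alleles camta3-1 and camta3-2 and the wild type. Values were log2 expression values of 22746 probe sets, after 64 control probe sets had been left out. Array medians lay between 6.18 and 6.26 on the log2 scale. Correlations across probe sets were 0.992 to 0.995 within a group and 0.986 to 0.994 between groups. Between mutant and wild-type arrays they were 0.986 to 0.989. Between the alleles they were 0.994 and 0.9937 for same-numbered arrays and 0.9926 and 0.9889 for the others. The replicates of camta3-1 and camta3-2 had 0.9929 and 0.9916, so same-numbered mutant arrays were more alike than replicates of an allele. The number of arrays limits the precision, and the median standard error of a log2 fold change was 0.11 for the mean of both alleles against wild type. The log2 difference between 3' and 5' control probe sets was 3.39 to 3.55 for actin, 0.14 to 0.46 for GAPDH and 1.19 to 1.33 for ubiquitin. The 2 camta3-2 arrays had the lowest ubiquitin values of all arrays, and their actin values lay above those of camta3-1. The CAMTA3 transcript was not analysed here, so the mutant labels were not checked against the targeted gene. Gene positions are not given, because the array files name no genome build.

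The first comparison asked which transcripts differ from wild type when CAMTA3 is mutated, from the mean of the 2 alleles with equal weight, so a gene that passed here need not pass in each allele alone. Transcripts of many named genes were higher in the mutants. The heavy-metal-associated domain gene AT5G52760 had the largest rise among named genes, from 3.86 ± 0.09 in wild type to 7.07 ± 0.83 in camta3-1 and 6.86 ± 0.12 in camta3-2 (log2, SD, n = 2 each). Its log2 fold change was 3.11 with a standard error of 0.28 (limma, adjusted p = 0.00411), an 8.63-fold rise. The leucine-rich repeat receptor kinase gene AT1G35710 rose by 3.10 on the log2 scale (standard error 0.31, adjusted p = 0.00562). The chitinase gene CHI, which encodes an enzyme that cleaves the chitin of fungal walls, rose by 2.81 (standard error 0.42, adjusted p = 0.0255).

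Further large rises were in genes of several kinds. The malectin-like receptor kinase gene AT5G59670 rose by 2.59 and the lipid-transfer protein gene AT5G55450 by 2.57 on the log2 scale. AT5G55450 had the smallest adjusted p of the named rises, 4.26e-04, with wild type at 8.39 ± 0.0028, camta3-1 at 11.38 ± 0.11 and camta3-2 at 10.54 ± 0.12 (SD, n = 2). The mannose-binding lectin gene AT5G18470 rose by 2.56, the aspartyl protease gene AT3G51330 by 2.50, the heavy-metal-associated domain gene AT5G52750 by 2.50 and the cytochrome P450 gene CYP71B23 by 2.47. The ubiquitin ligase gene RING1 rose by 2.08 (standard error 0.20, adjusted p = 0.00448). STZ, a zinc-finger transcription factor also called ZAT10, rose by 2.03 (standard error 0.18, adjusted p = 0.00393). AT1G13470, AT2G39210, AT4G00700 and AT5G19240 completed the 15 largest rises, at 2.78, 2.18, 2.17 and 2.07.

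Fewer genes fell. AT1G62510, a lipid-transfer protein-like gene, fell by 1.81 on the log2 scale (standard error 0.22, adjusted p = 0.0108), from 8.80 ± 0.23 in wild type to 6.89 ± 0.47 in camta3-1 and 7.09 ± 0.33 in camta3-2 (SD, n = 2). AT5G47330 fell by 1.66 (standard error 0.15, adjusted p = 0.00393). The polygalacturonase-type gene AT3G15720 had a 2.46-fold fall, and AT2G34930 fell by 1.27 on the log2 scale. THI2.1, a thionin gene known as a jasmonate response marker, fell by 1.26 (standard error 0.22, adjusted p = 0.0427). The transporter gene AT5G44050 fell by 1.11, the protein phosphatase gene AT3G05640 by 1.06 and AT1G69523 by 1.04. The plastid ribosomal protein gene rps14 fell by 0.97 and AT2G16990 by 0.92.

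**Figure D1:**
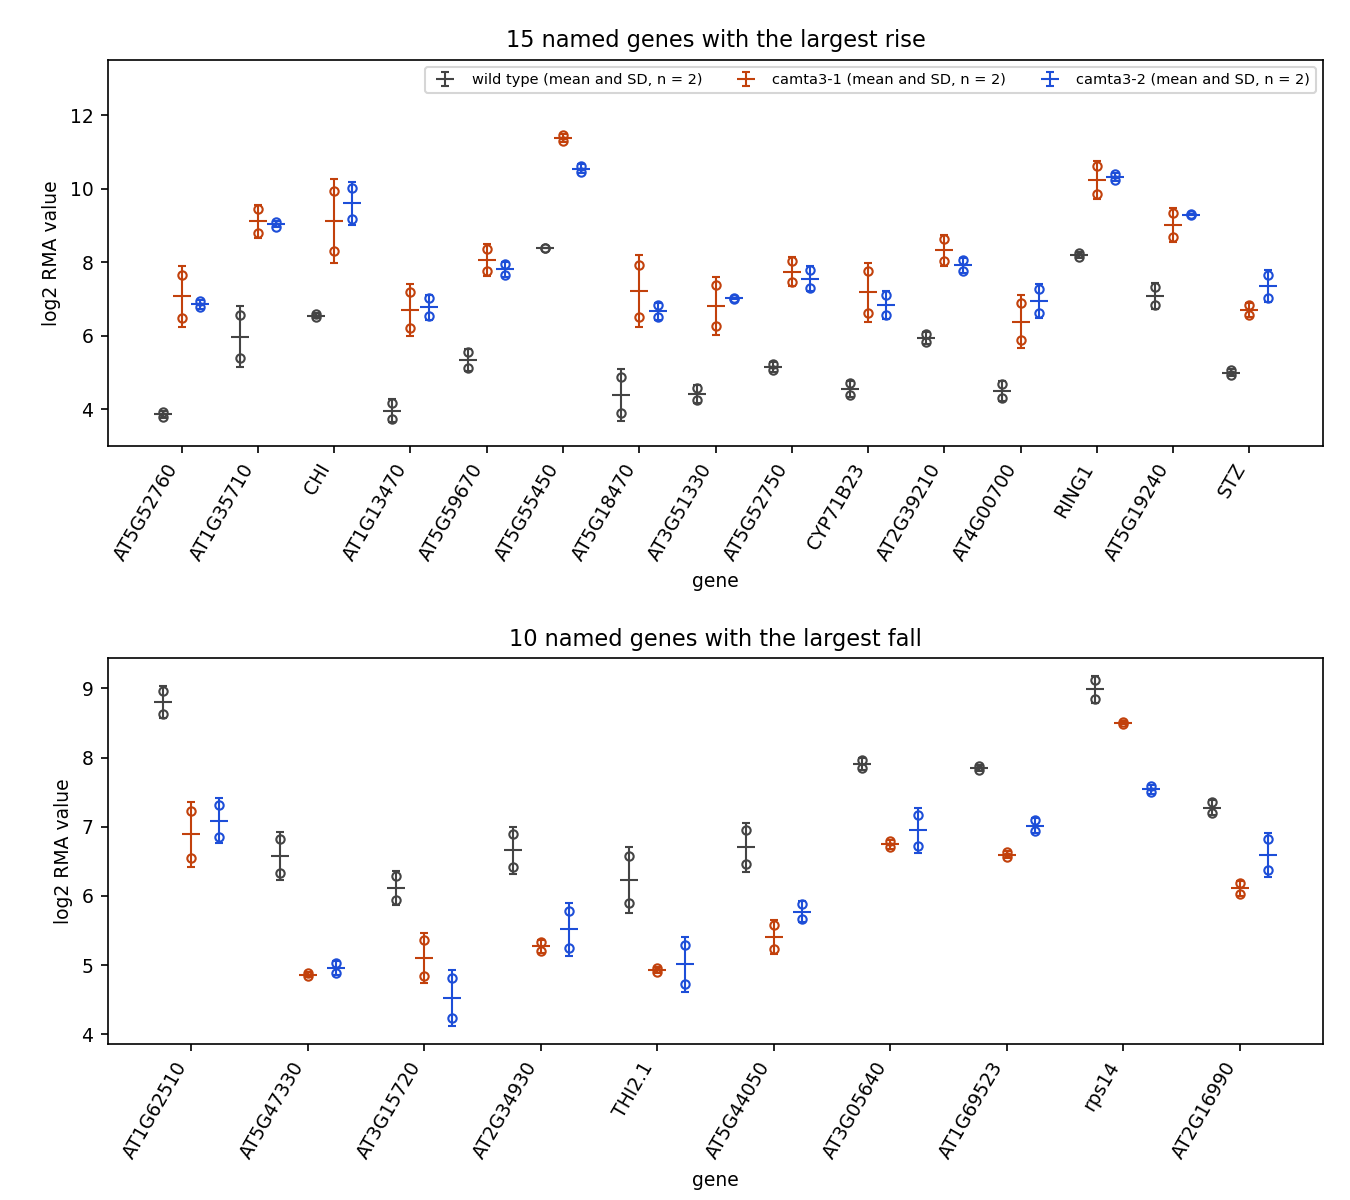
Log2 expression values per array of the 15 named genes with the largest rise (top) and the 10 with the largest fall (bottom) in the mean of both camta3 alleles against wild type, with open circles for arrays and bars for the mean and SD of 2 arrays per group. AT5G52760 lies at 3.86 in wild type and at 7.07 and 6.86 in the alleles, and all 4 mutant arrays lie on one side of both wild-type arrays for each gene drawn.

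Of the 22746 probe sets, 320 passed an adjusted p of 0.05 (limma), with 262 higher and 58 lower, and 190 of them changed at least 2-fold. The model treats the 4 mutant arrays as independent, while the deviations of same-numbered mutant arrays correlated at 0.402. The standard errors and p-values for the mean of both alleles may therefore be too small. All 4 mutant arrays lay above both wild-type arrays for 261 of the 262 higher probe sets, and below them for 58 of the 58 lower ones. Over all probe sets, 23.7% had no such overlap, against 13.3% by chance. Named genes accounted for 159 of the 320. The other 161 had none or several genes in the annotation used, and the largest change of all was among them, a log2 rise of 4.33 (standard error 0.26, adjusted p = 0.00187) for a probe set without a named gene. The counts rested on few arrays and on pooling the spread across probe sets, since 0 probe sets passed in the unmoderated test (2348 at an unadjusted p under 0.05), and 5 and 60 passed without wild type replicate 1 and 2. Most of 68 named gene calls no longer passed without wild type replicate 1 or 2. All kept their direction, which leaving out 1 array cannot reverse where mutant and wild-type arrays do not overlap.

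Gene groups were examined with lists fixed before the data were examined, of which 4 of 19 had at least 5 measured genes. In the list of pattern-triggered immunity receptors and kinases, the 5 measured genes were EFR, BIK1, PUB22, PUB23 and PUB24. Only EFR and BIK1 of these encode a receptor and a kinase. Of the 5 measured genes 1 rose, and 3 were higher when adjusted over the list alone. The gene that rose was PUB24, a U-box ubiquitin ligase known as a negative regulator of immune signalling. It rose by 0.98 on the log2 scale (adjusted p = 0.0479), and PUB22 and PUB23 did not pass. The receptor gene EFR and the kinase gene BIK1 had log2 fold changes of 0.33 and 0.38 (adjusted p = 0.253 and 0.28). Among 7 measured WRKY transcription factors, WRKY53 rose by 1.91 (adjusted p = 0.0171) and the other 6 did not pass, with 2 higher when adjusted over the list alone. None of the 5 measured calcium sensors passed, singly or over the list alone, and their mean log2 fold change was 0.26. Of the genes listed, 5 of 28 immunity, 7 of 72 WRKY and 5 of 17 calcium genes were measured, so most of each list was not seen. The WRKY genes had a mean log2 fold change of 0.43 and a median of 0.16, with WRKY53 far above both. As sets the measured genes of these 3 lists were shifted upwards, with camera adjusted p = 0.0128, 0.0172 and 0.0172 in that order. None of the 3 calls held with an estimated correlation, where adjusted p = 0.189, 0.189 and 0.237. Without wild type replicate 2 the calcium sensor list (adjusted p = 0.339) and the immunity list (adjusted p = 0.0541) did not pass, and the WRKY list did not pass without wild type replicate 1 (adjusted p = 0.0925) or camta3-2 replicate 2 (adjusted p = 0.0678). The 7 measured photosystem, light harvesting and Rubisco genes had a mean log2 fold change of -0.06, with camera adjusted p = 0.726.

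Of the other 15 fixed lists, 11 had 1 to 4 measured genes and were described without a set test, and 4 had none. Both measured rapid wound and touch response genes, WRKY53 and STZ, rose. The 3 measured cold response genes had negative log2 fold changes, and none passed over all probe sets. COR15A was at -1.21 (adjusted p = 0.0534), COR15B at -0.66 and COR47 at -0.58. When adjusted over the list alone, 3 of these 3 were lower. The 3 measured salicylic acid regulators were also 3 of 3 higher when adjusted over the list alone, with AT5G52810 (SARD4), an enzyme of pipecolic acid synthesis, at 1.36 (adjusted p = 0.0925 over all probe sets). Of the aliphatic glucosinolate genes measured, BCAT4 and AT2G31790, 2 were lower when adjusted over the list alone, and the nucleotide-binding receptor list had 1 of 2 higher in that way. THI2.1 was the 1 measured jasmonate gene, so adjusting over its list alone alters nothing and adds no support. In lists of so few genes this adjustment is slight. Of all probe sets, 13.4% were at an unadjusted p under 0.05 (limma). The defensin gene PDF1.2, an ethylene and jasmonate marker, had a log2 fold change of -0.89 (adjusted p = 0.588), and the wild-type arrays themselves differed widely, at 7.29 ± 1.77 (SD, n = 2). The related genes AT1G67310 (CAMTA4), AT4G16150 (CAMTA5) and AT3G16940 (CAMTA6) had log2 fold changes of 0.02, 0.04 and -0.18, with adjusted p = 0.965, 0.928 and 0.654. In the nucleotide-binding receptor list AT4G12010 was at 0.56 (adjusted p = 0.16). Of 3 measured senescence genes WRKY53 rose, with 1 higher when adjusted over the list alone, and SAG29 was at -0.42 (adjusted p = 0.865). None of 3 measured ethylene genes passed, and EIN3 was at 0.29 (adjusted p = 0.322). None of 2 measured heat shock genes passed, and the clock gene GI was at 0.07 (adjusted p = 0.836). The root marker EXPA7 had a log2 fold change of -0.07 (adjusted p = 0.807).

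A further 28 gene families were written after the coverage of the annotation had been seen but before any fold change was computed, and 23 had at least 5 measured genes. Members of the families chosen by locus were recalled, not taken from a curated table, so these families can be incomplete. In the family of TIR-domain immune receptors, proteins that sense pathogen effectors, 4 of 35 measured genes rose. AT3G04210 rose 2.83-fold (adjusted p = 0.0105). On the log2 scale AT1G66090 rose by 1.12, AT5G11250 by 0.91 and AT1G17600 by 0.75. Of 11 measured chitinases, 3 rose, with CHI joined by AT4G01700 at 1.89 (adjusted p = 0.0212) and AT1G02360 at 1.38 (adjusted p = 0.0479). Of 13 BCS1-like ATPases, AT1G43910 rose by 1.15 and AT5G17760 by 0.98. Of 7 glutamate receptor-like channels, GLR1.4 rose by 1.23 (adjusted p = 0.0435). Of 47 plastid-encoded genes, ndhG, a subunit of the plastid NADH dehydrogenase-like complex, fell by 0.67 (adjusted p = 0.0303), and the mean of the family was -0.27. In single alleles (limma) ndhG was at -1.04 in camta3-2 (adjusted p = 0.0155) and -0.30 in camta3-1 (adjusted p = 0.382). Its difference between the alleles did not pass. When adjusted over the list alone, 9 plastid-encoded genes were lower for the mean of the alleles, 0 in camta3-1 and 11 in camta3-2. The family median was -0.19 in camta3-1 and -0.17 in camta3-2, and the family was not shifted between the alleles (camera adjusted p = 0.852). The camta3-2 arrays stood apart in the ubiquitin control but not in GAPDH, and a link to the plastid genes was not tested. The plastid gene rps14, which also fell, lies outside that family as it was written. In camera these 5 families were shifted, with adjusted p = 1.66e-07 for TIR-domain receptors, 1.19e-06 for chitinases, 0.00799 for BCS1-like ATPases, 0.0171 for glutamate receptor-like channels and 1.01e-06 for plastid-encoded genes. None held with an estimated correlation, where adjusted p was 0.638 to 0.639. The number of shifted families was 8 without camta3-1 replicate 2 and 8 without wild type replicate 2. The glutamate receptor-like call was also lost above the 40th percentile of means (adjusted p = 0.223), without camta3-1 replicate 1 (adjusted p = 0.0545) and without camta3-2 replicate 1 (adjusted p = 0.0645).

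The remaining 18 tested families were not shifted as sets, and some held single genes that passed. Above the 40th percentile of means 3 of them did pass in camera, SWEET transporters (lower, adjusted p = 0.02), cytochromes P450 (higher, 0.0482) and trichome birefringence-like proteins (lower, 0.0482). The ankyrin-repeat membrane protein genes AT4G03450 and AT2G24600 rose by 1.80 and 0.93 on the log2 scale among 18 measured, and AT1G10340 rose 2.82-fold. The mean of that family was 0.19 and its median -0.01, opposite in sign. The malectin-like kinase genes AT5G59670 and AT5G59680 rose among 27 measured, and the mean and median of that family also had opposite signs, at 0.14 and -0.03. Of 23 cytochrome P450 genes, CYP71B23 and CYP71B22 rose. CYP71B22 was at 0.96 in camta3-1 (adjusted p = 0.0131) and 0.15 in camta3-2 (adjusted p = 0.665), and its difference between the alleles did not pass. The sugar transporter gene SWEET4 fell by 0.74 (adjusted p = 0.0153) and the beta-glucosidase gene BGLU33 by 0.64 (adjusted p = 0.028).

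**Figure D2:**
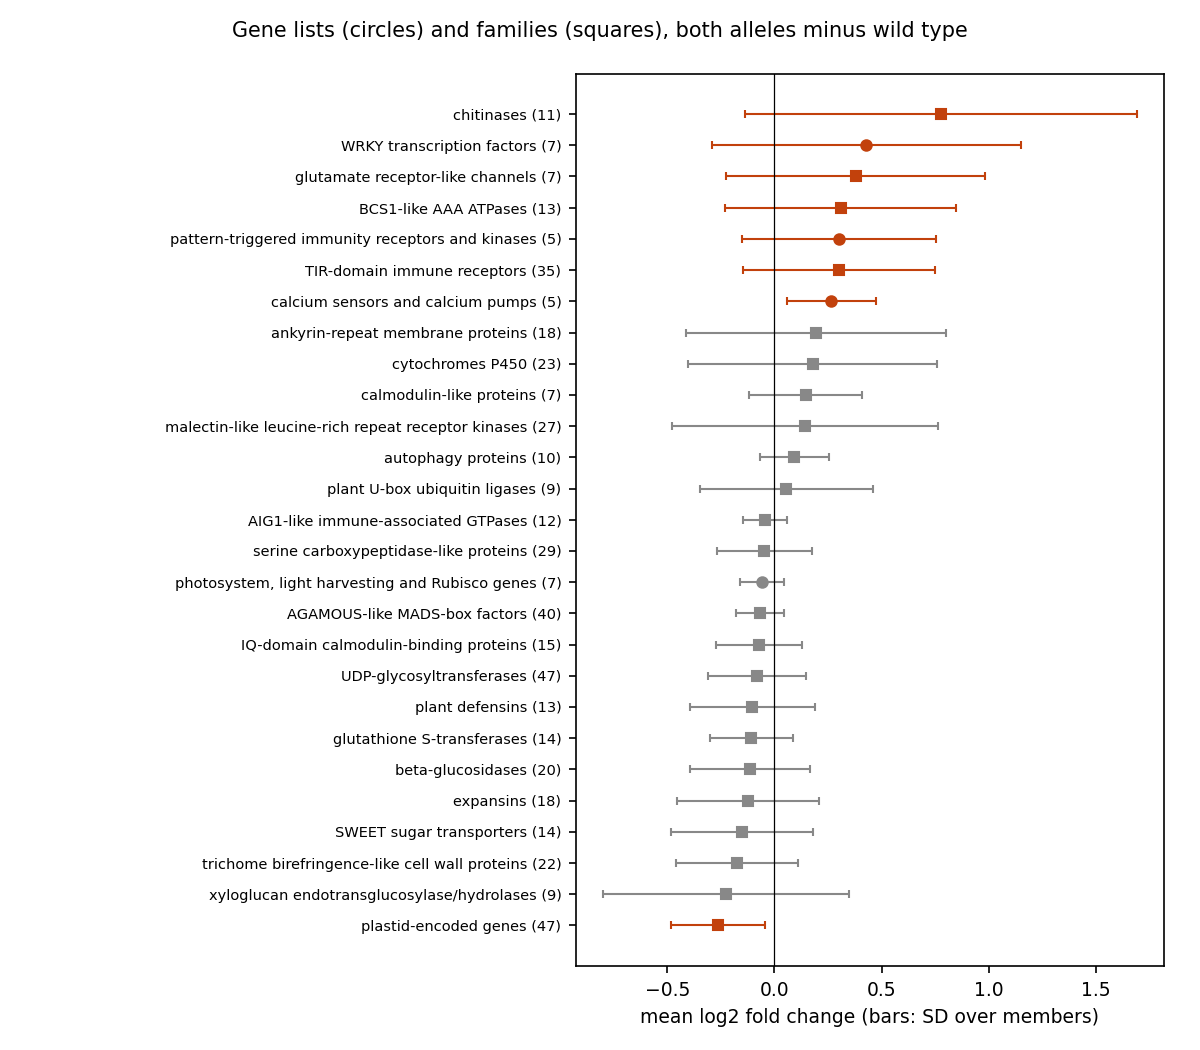
Mean log2 fold change of the measured members of each gene list (circles) and family (squares) in the mean of both camta3 alleles against wild type, with the number of members in parentheses and bars for the SD over members. Orange marks a camera adjusted p under 0.05 with the preset correlation, and the chitinases have the highest mean, 0.78, and the plastid-encoded genes the lowest, -0.27.

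Each allele was also compared with wild type on its own. In camta3-1 the largest named rises were AT5G52760, AT1G35710, AT5G55450, AT5G18470 and AT1G13470, at 3.22, 3.14, 3.00, 2.83 and 2.74 on the log2 scale. Among named genes that passed in camta3-1, the largest falls were AT1G62510, AT5G47330, AT2G34930 and TBL26, at -1.91, -1.71, -1.39 and -1.37, with AT5G44050 next. In camta3-2 the largest named rises were AT1G35710, CHI, AT5G52760, AT1G13470 and AT3G51330, at 3.06, 3.06, 3.00, 2.81 and 2.60. Among named genes that passed in camta3-2, the largest falls were AT1G62510, AT5G47330, AT3G15720, rps14 and AT2G06480, at -1.71, -1.62, -1.59, -1.45 and -1.18. TBL26, a cell wall acetylation-type gene, had a log2 fold change of -0.40 in camta3-2 (adjusted p = 0.406), and the difference between the alleles, 0.97, did not pass (adjusted p = 0.597).

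In camta3-1, 246 probe sets passed, with 183 higher and 63 lower, and in camta3-2, 167 passed, with 149 higher and 18 lower (limma). Leaving out one array moved these counts by more than 1.5 times in several cases. The camta3-1 count was 114 without camta3-1 replicate 1, 2 without wild type replicate 1 and 38 without wild type replicate 2. The camta3-2 count was 270 without either camta3-1 array, 11 and 55 without camta3-2 replicate 1 and 2, and 5 and 42 without wild type replicate 1 and 2. In the unmoderated test 0 passed for either allele, with 2174 and 2042 at an unadjusted p under 0.05.

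Gene groups were tested in each allele as well. In camta3-1 the immunity list and the WRKY list were shifted upwards, with camera adjusted p = 0.0355 and 0.0392, and both had adjusted p = 0.217 with an estimated correlation. In camta3-2 the calcium sensor, immunity and WRKY lists were shifted upwards, with adjusted p = 0.00809, 0.00809 and 0.0302, and all had adjusted p = 0.186 with an estimated correlation. Of the families, TIR-domain receptors and chitinases were shifted upwards and plastid-encoded genes downwards in both alleles, with the largest camera adjusted p at 1.23e-04. BCS1-like ATPases and glutamate receptor-like channels were shifted upwards in both (adjusted p = 0.0309 and 0.0414 in camta3-1, 0.0071 and 0.0242 in camta3-2), and trichome birefringence-like proteins downwards in camta3-1 (adjusted p = 0.047). With an estimated correlation none of these passed, the smallest adjusted p being 0.551. Between the alleles no list or family was shifted, and the smallest camera adjusted p was 0.0893.

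The changes in the alleles were set against each other and against simulated unchanged groups, because both comparisons use the same 2 wild-type arrays. Among the probe sets higher in each allele, 125 were higher in both, and AT5G52760, AT1G35710, AT5G55450 and RING1 were among them. That count was 77 and 214 without camta3-1 replicate 1 and 2, 6 and 29 without camta3-2 replicate 1 and 2, and 1 and 30 without wild type replicate 1 and 2. In 100 simulations with shared wild-type arrays and independent probe sets, lists of the same sizes had 32.28 probe sets in common on average and at most 46. With same-numbered mutant arrays also correlated at the observed 0.402, they had 54.66 on average and at most 68. For the probe sets lower in each allele the 7 in common were within the simulated values, which averaged 5.18 and reached 9 with shared controls alone. Of the 246 probe sets that passed in camta3-1, 246 had the same sign in camta3-2, and of the 167 in camta3-2, 166 had the same sign in camta3-1, the exception being QQS. Shared controls alone gave 223 and 152 on average and at most 232 and 160, and correlated mutant arrays gave up to 245 and 167. No probe set passed in opposite directions.

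Across probe sets, which are not independent replicates, the log2 fold changes of the alleles correlated at r = 0.786. With shared controls and independent mutant arrays r averaged 0.501 in simulations, and with correlated mutant arrays it averaged 0.701 and reached 0.72. The covariance was 0.070, against averages of 0.0122 and 0.017. The matched lists, the correlated arrays and the divided controls were added after the agreement had been seen. With a different wild-type array for each allele, so that no control was shared, r was 0.547 and 0.598 for the 2 ways of dividing them. Simulated unchanged groups divided in these ways gave at most 0.0467 with independent and 0.167 with correlated mutant arrays. In all the simulations the probe sets were drawn independently of each other. Where probe sets vary together, values of unchanged groups could spread more widely, so the simulated maxima are not limits for real arrays. A difference between the wild-type arrays and all mutant arrays that is unrelated to the mutation was not tested.

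**Figure D3:**
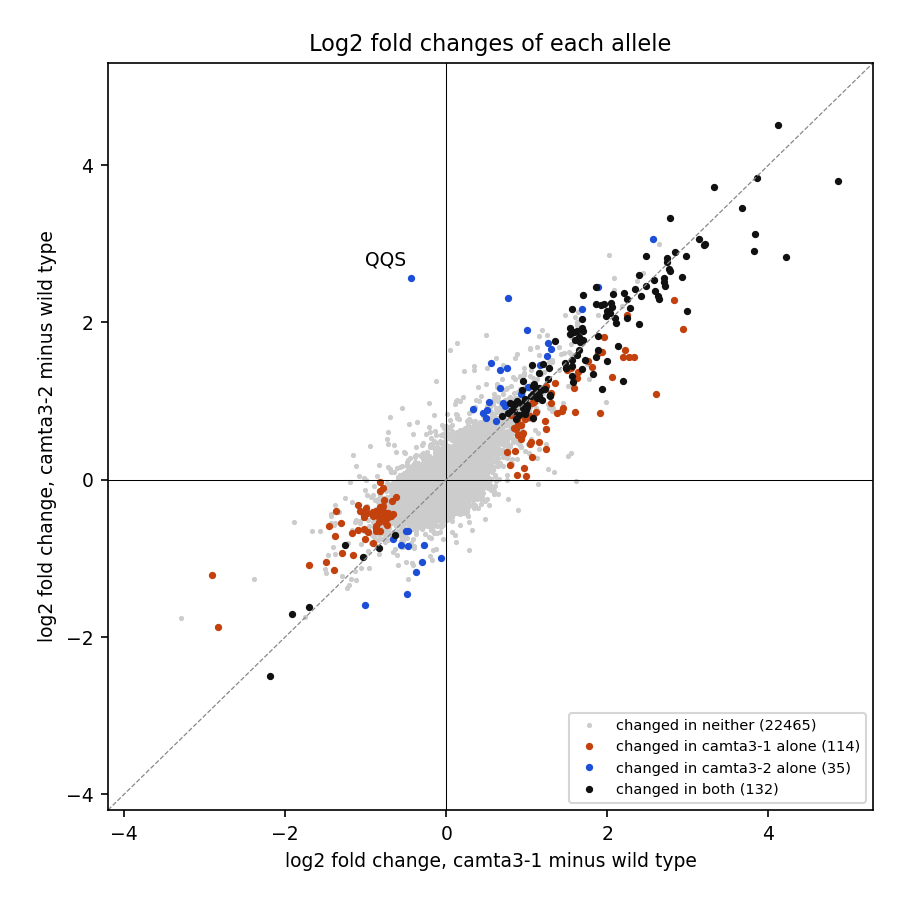
Log2 fold change of each of 22746 probe sets in camta3-1 (x axis) and camta3-2 (y axis) against wild type, coloured by the allele in which it passed an adjusted p of 0.05, with the dashed line at equal change. The 132 probe sets that passed in both alleles lie along the dashed line with the same sign in both, and QQS lies apart at -0.43 and 2.57.

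The alleles were compared with each other to find transcripts that differ between them. QQS, an orphan gene that affects starch content, was 3.00 higher on the log2 scale in camta3-2 than in camta3-1 (standard error 0.13, limma adjusted p = 8.36e-04). Its level was 5.83 ± 0.04 in camta3-1, 8.83 ± 0.16 in camta3-2 and 6.27 ± 0.15 in wild type (log2, SD, n = 2). QQS rose by 2.57 against wild type in camta3-2 (adjusted p = 8.72e-04), and its log2 fold change in camta3-1 was -0.43 (adjusted p = 0.23). It was the 1 probe set of 22746 that passed, with 1442 at an unadjusted p under 0.05. The count was 2 without camta3-2 replicate 1 and 7 without camta3-2 replicate 2, and 0 in the unmoderated test (1210 at an unadjusted p under 0.05).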

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

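The test of replicate spread for QQS was chosen after the result was seen, and the test of its neighbours before. QQS stood out because the difference between the 2 alleles passed its own test, with a log2 difference of 3.0006 between camta3-2 and camta3-1. The largest log2 difference between replicates of any group was 0.2329, so both arrays of each allele showed the difference. A call at this threshold already needs close replicates, so the test adds no separate evidence against a single aberrant array. Of the 20 nearest measured loci in gene order, 0 differed between the alleles at an unadjusted p under 0.05, where 1.27 would be expected. The largest absolute log2 difference among them was 0.22. This argues against a segment around QQS that alters many transcripts of these neighbours in one line. A differing segment that leaves them unaltered stays open. A change at QQS itself that differs between the mutant lines, whether linked to CAMTA3 or not, may remain and was not tested.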

How the results depend on the processing

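The families and their alternatives were added after the annotation was seen. Of 1082 comparisons of named gene calls with an alternative, all 1082 kept their direction and 754 also passed, and 328 no longer did. Direction could not reverse in many of these. The unmoderated test, another prior and a stricter threshold leave the fold change unaltered. Leaving out 1 array cannot reverse a gene whose mutant and wild-type arrays do not overlap. Counts for the mean of both alleles, camta3-1 and camta3-2 were 320, 246 and 167. They became 493, 430 and 280 with a replicate block, where the deviations of same-numbered arrays correlated at 0.402 between the mutants, -0.04 between camta3-1 and wild type and 0.13 between camta3-2 and wild type, so the numbers were not taken as pairing the arrays. With the block the higher calls became 360, 283 and 241, from 262, 183 and 149. The lower calls became 133, 147 and 39, from 58, 63 and 18. The block left the count between alleles at 1 and changed no list or family call for both alleles. Lists were not run with it in each allele alone. The counts became 0, 0 and 0 in the unmoderated limma model (2348, 2174 and 2042 at an unadjusted p under 0.05; smallest adjusted p 0.328, 0.327 and 0.34), and 0 for the difference between alleles (1210; 0.424). They became 83, 37 and 30 at an adjusted p under 0.01 and 166, 112 and 67 with probe sets of 1 gene, where fewer probe sets can be called. At least 2-fold left 190 for both alleles, and fitting only camta3-2 and wild type gave 270. Leaving out one array gave 5 to 458 for both alleles, 2 to 333 for camta3-1, 5 to 270 for camta3-2 and 1 to 7 between alleles, where a group left with 1 array is assumed to vary like the others. The lowest counts against wild type came without wild type replicate 1. Leaving out wild type replicate 2, the same design, gave 60 for both alleles, so the number of arrays does not account for the difference, and its cause was not tested. The correlation of the alleles was 0.6578 to 0.8217.

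Of the fixed lists, 3 passed, and 1 to 3 did without one array. None passed with an estimated correlation (0) or with fry (0), which tests whether genes of a list move one way. Above the 40th percentile 1 list still had 5 genes, that of the photosystem genes, and it did not pass (camera adjusted p = 0.62). The 3 lists that passed could not be tested there. Of the added families, 5 passed, 4 to 8 without one array, 6 above the 40th percentile (3 of the 5 and 3 others), and 0 with an estimated correlation and 0 with fry. The estimated-correlation test uses 3 residual degrees of freedom, which limits it. Direction reversed in 10 of 369 list and family comparisons, none past the threshold. The adjusted p values there were 0.859 without camta3-1 replicate 2 and 0.682 without wild type replicate 1 for photosystem genes, 0.969 with cyclic loess, 0.893 without camta3-1 replicate 2 and 0.93 without wild type replicate 1 (0.684 without wild type replicate 2) for AIG1-like GTPases, 0.988 above the 40th percentile and 0.775 without wild type replicate 1 (0.486 without wild type replicate 2, 0.96 without camta3-1 replicate 1) for serine carboxypeptidase-like proteins, 0.968 without camta3-2 replicate 2 (0.0154, lower, without camta3-2 replicate 1) for UDP-glycosyltransferases, 0.87 without wild type replicate 2 (0.011, higher, without wild type replicate 1) for calmodulin-like proteins and 0.863 without wild type replicate 2 (0.317 without wild type replicate 1) for plant defensins. The cause was not tested. The promoter element counts and the CAMTA3 transcript were planned and not run. Dim probe sets limit what the arrays show, since RMA compresses values near background.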

Other observations

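Further genes that passed for the mean of the alleles against wild type (limma), not always in each allele, were chosen after their values were seen and were not tested as groups. The legume lectin genes AT5G03350 and AT3G16530 rose by 1.69 and 1.64 on the log2 scale, and AT5G03350 was at 10.79 ± 0.28 in wild type, 12.32 ± 0.27 in camta3-1 and 12.65 ± 0.19 in camta3-2 (SD, n = 2). The secreted cysteine-rich repeat genes AT3G22060 and AT5G48540 rose by 1.95 and 1.78. The receptor kinase genes AT4G08850 and AT1G11330 rose by 1.71 and 1.46, with adjusted p = 0.00411 and 0.00544. Of TIR-domain receptor genes outside the family tested, AT5G36930 and AT4G36150 rose by 0.90 and 0.76. The calcium-binding protein genes AT2G41090 and AT2G41410 rose by 1.27 and 0.96. The calmodulin-like family tested was chosen by symbol pattern, so it misses genes named by locus alone, as these are. In it 0 of 7 measured genes passed (limma) and the camera adjusted p was 0.195, which does not speak for calmodulin-like genes left out. AT3G48080, a paralogue of the immune regulator EDS1, rose by 1.87 (adjusted p = 0.00898). Of the wall-associated kinases, an added family with too few measured genes for a set test, 2 of 4 measured rose, AT1G69730 by 1.16 and AT1G16260 by 0.83.

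Most falls were smaller. The cellulase-type gene GH9B8 fell by 0.74 and AFR, a gene of light signalling, by 0.61 on the log2 scale (adjusted p = 0.036 and 0.0343). Of the 40 measured loci nearest CAMTA3 in gene order, 0 passed for the mean of the alleles against wild type and 4 were at an unadjusted p under 0.05 (limma), against 13.4% of all probe sets. The 2 largest falls, at -2.35 and -2.34 on the log2 scale, belonged to probe sets without a single named gene.

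The test of a batch shared by a replicate number was chosen after the correlations were seen, and the test without changed probe sets was written before. The replicate differences of the 2 mutants correlated at 0.402 across probe sets. The wild-type difference correlated with those of camta3-1 and camta3-2 at -0.0367 and 0.1345. A batch that altered all arrays of a number alike would raise both, and these values are low. The rule was set with the values known, so the test adds no separate evidence against such a batch. Over the 19702 probe sets left without those at an unadjusted p under 0.05, the correlation between the 2 mutants was 0.4169, so it was not confined to called genes. This test cannot decide on a stronger response of the raised genes in replicate 1 of both mutants. The probe sets left can include small responses, and large replicate differences themselves raise p. Over the 262 raised probe sets, the median log2 difference of replicate 1 minus replicate 2 was 0.40 in camta3-1, 0.12 in camta3-2 and -0.12 in wild type. The difference was above 0 in 241, 176 and 81 of them, the direction of a stronger response in both mutants. Over all probe sets the median was -0.0047 in camta3-1, 0.0504 in camta3-2 and -0.0066 in wild type. Part of the camta3-2 difference can therefore be a shift of the whole array. Over the 58 lowered ones the median was 0.08 and 0.15 in camta3-1 and camta3-2 (above 0 in 41 and 46). A stronger response that included the lowered genes would place these below 0. A stronger response of the raised genes and a batch that held only mutant arrays may remain open, and no other biological explanation was tested.

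The test of chance positions was written before its result was seen, and the test of probe set marks is counted as chosen after, since some of these probe sets had been seen. Of the 119 named loci that were higher for the mean of the alleles, 6 lay next to another in the order of 13286 measured loci, as the pairs CYP71B22 and CYP71B23, AT5G52750 and AT5G52760, and AT5G59670 and AT5G59680. In 10000 random draws of 119 loci the count averaged 2.1 and reached 14, and the one-sided permutation p was 0.08, so chance could give this number. Hybridisation to both genes of a pair stays open, because 0% of these neighbours were measured by probe sets marked as shared but only 2.1% of all measured loci could be, after probe sets with several genes had been left out. Similar sequences that such marks miss were not tested.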
